A study of Drosophila melanogaster with 4 samples.

How the data were processed

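Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 monomethylated at lysine 4 (H3K4me1) in S2-DRSC cells. These cells are an established Drosophila melanogaster line derived from late embryos and labelled male. Per the labels, 2 libraries were made from chromatin precipitated with an affinity-purified rabbit polyclonal antibody against H3K4me1 and 2 from input DNA. Per the labels' protocols, cells were fixed with formaldehyde and the chromatin was sonicated. Input DNA is the sheared chromatin before precipitation, which serves as the background of a ChIP-seq experiment.

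The data used here were 1 peak list for the whole series. Per the file headers the coordinates are on FlyBase release 5, and the source column names MACS, a peak caller that compares the pileup of ChIP reads with a local background. The submitters' processing notes name the CASAVA software (versions 1.7.0.2 and 1.7.0.3), the BWA aligner, the MACS2 peak caller and the BDGP5 genome build, without roles or order. How the 2 ChIP libraries were combined, the threshold for a peak and the treatment of reads that match several places are not given in the sources used here. The authors deposited a score for each peak, and neither the header nor the labels give its scale. Scores were therefore compared only within this list, mostly by rank. Where a correlation or a difference of the values themselves is given, it holds on that unknown scale. Because repeated sequence can take reads from many copies, the unknown treatment of such reads affects what a high score on such sequence means. Other values deposited by the authors are the start and end of each peak. The lowest start in the file is 0, so starts were taken to count from 0, and all positions printed here count from 1. A peak's width is the file's end minus its start.

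No value per library was used, so the ChIP libraries were not compared with each other or with the input, and the read depth was not analysed here. Errors are therefore spreads over peaks or over blocks of the genome, not over biological replicates, and the tests measure only whether a pattern within this list exceeds the spread between blocks or random placement. The reference table of genes at hand is on Release 6, a different build from release 5 of the peaks. Coordinates were not converted between builds. Position relative to genes, coverage around transcription start sites, the fixed gene lists and sequence composition were not analysed here, and no gene is named.

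Peaks were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each arm was tiled with 100-kb blocks from its first to its last peak, and the share of bases inside peaks was computed per block. A final piece shorter than 50 kb was added to the block before it. For score percentiles, blocks were counted from the first base of each sequence and peaks were assigned by midpoint. Only blocks that hold a peak entered there, each with the same weight. Chromosome X and chromosome 4 were each compared with the 4 large autosomal arms by a two-sided permutation test of the block means with 100000 permutations, and the p-values were adjusted over these 2 comparisons by the Benjamini-Hochberg method. Intervals are 95% percentile intervals from 10000 bootstrap resamples of blocks. Intervals for a share of blocks are exact binomial intervals at 95%. Clustering was measured as the share of neighbouring peaks less than 2000 bases apart, against 1000 placements in which the same peaks of each sequence were placed at random without overlap. Score and width were compared across peaks by Spearman's rho with 100000 permutations. Peaks are not independent replicates.

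The designs, alternatives and naming rule were fixed before the data were examined. Peaks named by position are the 10 with the highest score, the 10 widest, and the highest and the widest of each of 2L, 2R, 3L, 3R, 4 and X. Other named regions were chosen after their values were seen, and the text says so. The comparison of all pairs of arms, the comparisons of score ranks and the search for recurring widths were also chosen after seeing the data. The alternatives were stricter score thresholds, joining of peaks less than 500 bases apart, other block sizes, peak number in place of covered bases, other gaps, removal of peaks under 300 bases and restriction to the 6 arms.

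The block, placement and width procedures were tested on simulated data. In simulated lists of 7992 peaks, the X test called 20 of 20 lists in which X had 0.7 of the autosomal density and 0 of 20 lists with no difference. Peaks in these lists were placed at random, while those of the real list lay in clusters. The counts therefore do not give the rates of calls for clustered peaks. Random lists of that size fell outside the range of the random placements in 0 of 20 cases. The pair count for recurring widths jitters the 646 arm peaks of 3000 bases or more and counts pairs among those of 4000 bases or more, since a first version without this margin called too many simulated lists with nothing planted. In simulated lists of 646 peaks, it called 20 of 20 lists with 25 planted peaks of nearly the same width and 0 of 20 without. The test for shared scores used the simulated peaks of 4000 bases or more, a median of 345 per list, and called 18 of 20 lists with the planted peaks and 1 of 20 without. The scan over windows of width and the comparison of scores within a window were not tested on simulated data.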

Results

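The series mapped H3K4me1, a histone mark known from enhancers and from the flanks of active promoters, in the Drosophila cell line S2-DRSC, with 2 ChIP libraries and 2 input libraries. The peak list held 11173 peaks on 14 sequences, with a summed length of 10.8 Mb. The 6 chromosome arms carried 8019 peaks, or 71.8% of the list. The other 3154 peaks, 28.2%, lay on sequences outside the arms, which are the heterochromatic Het scaffolds and the collections U and Uextra of sequence not placed on an arm. The median peak was 556 bases wide, with quartiles of 344 and 995 bases. The narrowest peaks were 200 bases wide, a width shared by 154 peaks. The widest 5% of the peaks, 559 peaks of 3421 bases or more, held 27.0% of the summed length. The authors' score had a median of 23.6 and ran from 6.06 to 563. Read depth and values per replicate were not used here, so each count describes this list alone.

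The first comparison asked how the mark was spread over the arms. Among the large arms, 2R was the most densely covered and X the least. On 2R, 1930 peaks covered 10.2% ± 9.57 of each 100-kb block (mean ± SD, n = 211 blocks). On 3R, 2126 peaks covered 8.33% ± 8.35 (SD, n = 279 blocks), and on 3L, 1643 peaks covered 7.49% ± 9.18 (SD, n = 245 blocks). On 2L, 1265 peaks covered 5.76% ± 6.88 (SD, n = 230 blocks). On X, 1029 peaks covered 5.47% ± 8.66 (SD, n = 224 blocks).

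**Figure D1:**
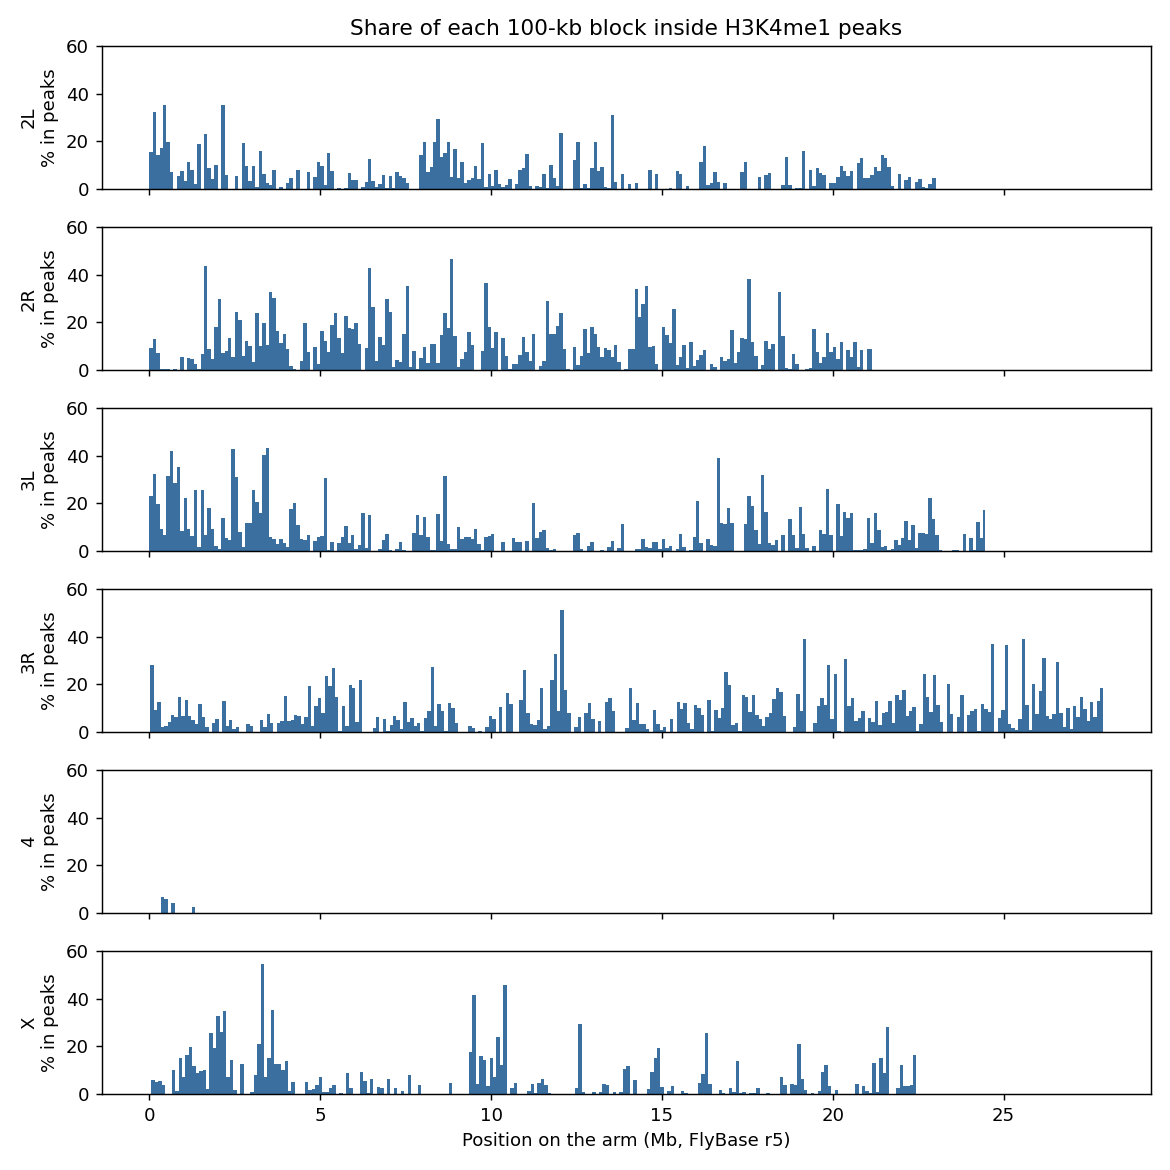
Share of each 100-kb block inside peaks (percent, vertical axes) along each arm (horizontal axis, Mb on FlyBase r5), with 1 bar per block and blocks running from the first to the last peak. Covered blocks alternate with empty stretches on every arm, and the block with the highest share, 54.6%, lies on X between 3257201 and 3357200.

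S2-DRSC cells are labelled male, and in male flies the single X is known to be transcribed at a raised rate by dosage compensation, so X was compared with the autosomal arms. X blocks were less covered than the blocks of the 4 large autosomal arms, which averaged 7.91% ± 8.66 (SD, n = 965 blocks). The difference was -2.44 percentage points, with a 95% interval from -3.65 to -1.14 (permutation test, p = 0.00026, adjusted p = 0.00052). X also held more empty blocks. There were 65 of 224 blocks without any peak base on X, or 29.0% (exact 95% interval 23.2 to 35.4), and 147 of 965 on the autosomal arms, or 15.2% (13.0 to 17.7). The exact intervals treat blocks as independent. Empty blocks on X lay partly in runs, so the intervals may be too narrow. The longest stretch without a peak on X ran from 8002833 to 8816323 and measured 813491 bases, chosen after the values were seen. Peaks that were present on X ranked higher by score when averaged per block. Over single peaks the median score was 19.05 on X and 17.89 on the autosomal arms. Over blocks that hold a peak, the mean score percentile among peaks of the 5 large arms was 57.6 on X (n = 150 blocks) and 50.6 on the autosomal arms (n = 815 blocks). The difference was 7.02 (95% interval 2.80 to 11.2, permutation test, p = 7e-05). Without the 1 Mb nearest the centromere, this difference was 6.90 (2.51 to 11.2, p = 0.00013 by permutation). Without peaks scoring over 100, a cut on the score itself, it was 1.93 (-2.08 to 5.93, p = 0.244 by permutation). Among the highest-scoring 25% of the peaks, the difference in covered bases was -0.24 points (adjusted p = 0.516 by permutation). Over blocks that hold a peak it was -1.62 points (adjusted p = 0.0662 by permutation).

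The autosomal arms also differed among themselves. Of the 10 pairs among the 5 large arms, 8 differed at an adjusted p under 0.05 in the permutation test, and 5 of the 6 pairs of autosomal arms were among them. All 4 pairs with 2R passed. 2L minus 2R was -4.43 points (95% interval -6.01 to -2.85, adjusted p = 5e-05 by permutation), although both are arms of the same chromosome. X and 2L differed by 0.29 points, with an interval from -1.15 to 1.74 (adjusted p = 0.693 by permutation), so X was not set apart from every autosomal arm. Neighbouring blocks are not fully independent, and with 500-kb blocks the adjusted p of X against the autosomal arms was 0.0123.

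**Figure D2:**
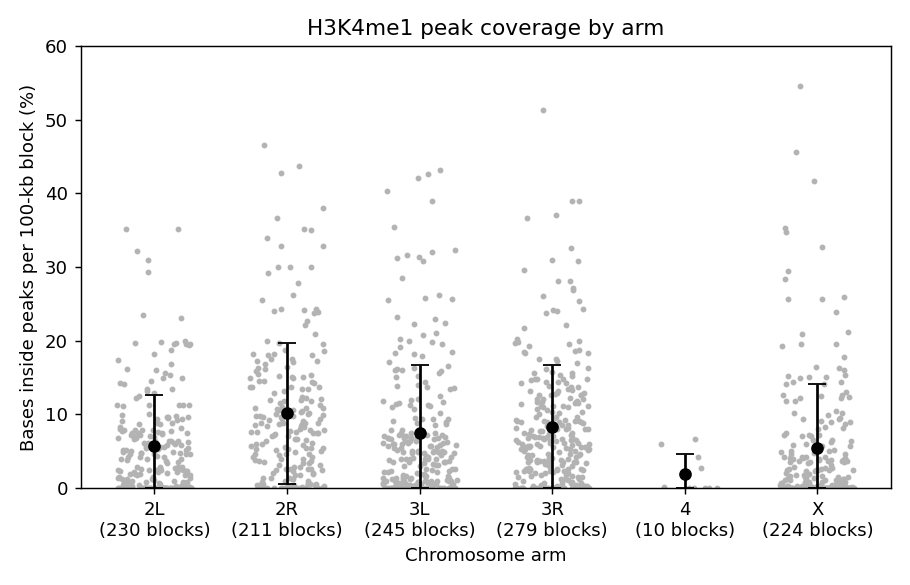
Bases inside peaks per 100-kb block (percent, vertical axis) on each arm (horizontal axis, with the number of blocks). Grey points are blocks, black points are means and bars are 1 SD, cut off at 0. Means run from 1.98% on chromosome 4 to 10.2% on 2R, and blocks of every arm overlap.

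Chromosome 4, a small chromosome known to be largely packed as heterochromatin, held 26 peaks with a summed length of 19257 bases. Its blocks were covered to 1.98% ± 2.71 (SD, n = 10 blocks), 5.93 points less than the autosomal arms, with an interval of the difference from -7.48 to -4.18 (permutation test, p = 0.0295, adjusted p = 0.0295). No base lay in a peak in 5 of the 10 blocks. Its first peak began at 340687, and its highest-scoring peak lay at 692235 to 694457 with a score of 230. Its widest peak lay at 525937 to 529084, with 3148 bases and a score of 36.3. With 10 blocks the test was near its threshold, and the call was lost under 3 settings, although the mean stayed lower in each. Among peaks at or above the median score the means were 1.47% on chromosome 4 and 5.68% on the autosomal arms (adjusted p = 0.0582 by permutation). Among the highest-scoring 25% they were 0.56% and 2.99% (adjusted p = 0.21 by permutation), and over blocks that hold a peak 3.96% and 9.33% (adjusted p = 0.149 by permutation). The call was kept under 7 other settings. Tiling from the first peak leaves out the stretch before it. With blocks from base 1, chosen after seeing the data, coverage was 1.45% over 13 blocks, against 7.90% on the autosomal arms (adjusted p = 0.00953 by permutation).

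Peaks lay in clusters. Of 11159 pairs of neighbouring peaks, 5249, or 47.0%, were less than 2000 bases apart. Random placement gave 14.3% on average and at most 15.3% (permutation of positions, p = 0.001, the smallest that 1000 placements can give). On the 5 large arms the share was 56.2%, against at most 15.2% by random placement, and on chromosome 4 13 of 25 pairs were that close, against 5.12% of pairs by random placement on average. X and the autosomal arms had similar shares, 56.8% and 56.1%, and their difference was not tested. On Uextra the share was 20.4%, against a random mean of 16.7% and at most 18.7%. Since U and Uextra are collections of unplaced sequence, a distance between neighbours there need not be a distance in the genome. The Uextra value is therefore not interpreted. Its 2521 pairs are among the 11159, so the shares on the arms are the firmer ones. The smallest gap between neighbours was 51 bases. Joining peaks less than 500 bases apart left 8088 domains, of which 47 were over 10 kb, and 26.8% of the neighbouring domains were still less than 2000 bases apart, against at most 12.2% by random placement.

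Wider peaks had higher scores. Across the 11173 peaks, Spearman's rho between score and width was 0.63 (permutation p = 1e-05, the smallest that 100000 permutations can give). Pearson's r between score and log10 width was 0.47 (permutation p = 1e-05). Within the 5 large arms rho was 0.81 and within Uextra 0.67, each with a permutation p of 1e-04, the smallest that 10000 permutations can give. Among peaks at or above the median score, a list cut on the score itself, rho was 0.18. Peaks are not independent replicates, so these values describe the list.

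The 10 widest peaks all lay on arms, 3 on 3R, 3 on 3L, 2 on X, 1 on 2L and 1 on 2R. The widest covered 19468 bases of 3R from 11830996 to 11850463, with a score of 134. It was followed by 14437 bases of 3L from 2565906 to 2580342, with a score of 105, and by 13781 bases of 3L from 3377910 to 3391690, with a score of 403, which was also the highest-scoring peak of 3L. The widest peak of 2L covered 13178 bases from 494707 to 507884, that of X 13168 bases from 17180711 to 17193878, and that of 2R 11085 bases from 1614665 to 1625749.

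The 10 highest-scoring peaks were placed differently, with 8 on Uextra, 1 on U and 1 on an arm. The highest was on Uextra from 24193645 to 24194457, with a width of 813 bases and a score of 563. The highest on an arm lay on 3R from 27895661 to 27905153, with a width of 9493 bases and a score of 506. It was the last peak of 3R on the side of the telomere. The highest-scoring peak of 2R, from 21145631 to 21146802 with a score of 404, was likewise the last of its arm. The highest of X lay at 21588135 to 21591395, with a score of 264. The highest of 2L lay at 20303154 to 20310648, with a width of 7495 bases and a score of 274. This width recurred. On the 6 arms, 22 peaks were between 7468 and 7568 bases wide, and 19 of these scored 200 or more.

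**Figure D3:**
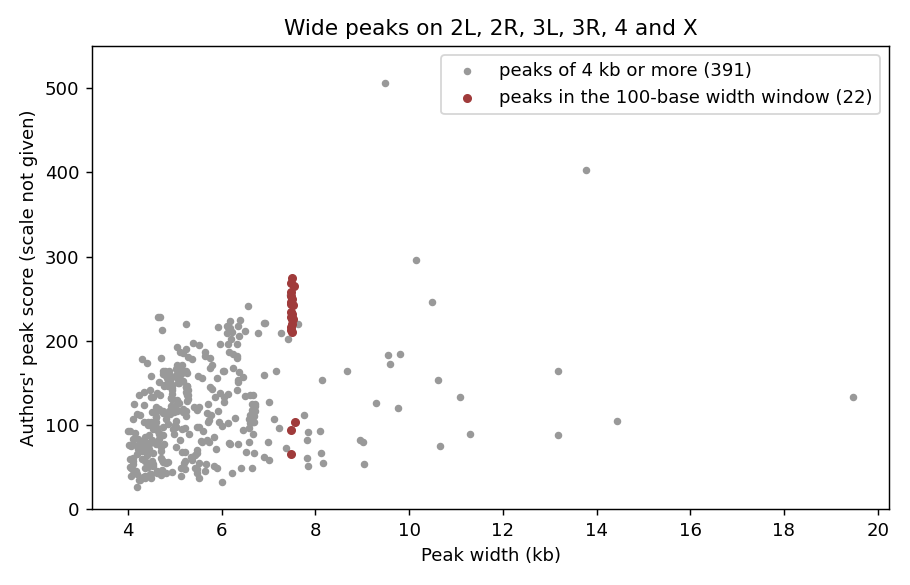
Authors' score (vertical axis, scale not given) against width (horizontal axis, kb) for the 391 peaks of 4 kb or more on the 6 arms, with 1 point per peak. The 22 peaks between 7468 and 7568 bases, in red, form a column whose median score is 230.

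Outside the arms, scores were higher. Uextra held 2522 peaks, 22.6% of the list, with a median score of 59.9 and a median width of 503 bases. U held 361 peaks with a median score of 68.2, and the Het scaffolds held 271 peaks with a median score of 41.9. The 5 large arms had a median score of 17.9. The mean score percentile per 100-kb block was 70.9 ± 13.5 outside the arms (SD, n = 443 blocks) and 44.2 ± 20.2 on the 5 large arms (SD, n = 965 blocks). The difference was 26.7 (95% interval 24.9 to 28.5, permutation test, p = 1e-05, the smallest that 100000 permutations can give). Blocks on U and Uextra are cut from collections of unplaced sequence, so they are not stretches of the genome and need not be independent. The interval and p therefore describe the list and not a spread over the genome. On lists cut on the score itself the difference was 15.4 at or above the median score and 2.01 among the highest-scoring 25% (p = 0.188 by permutation). Of the highest-scoring 25% of the peaks, 58.8% lay outside the arms.

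**Figure D4:**
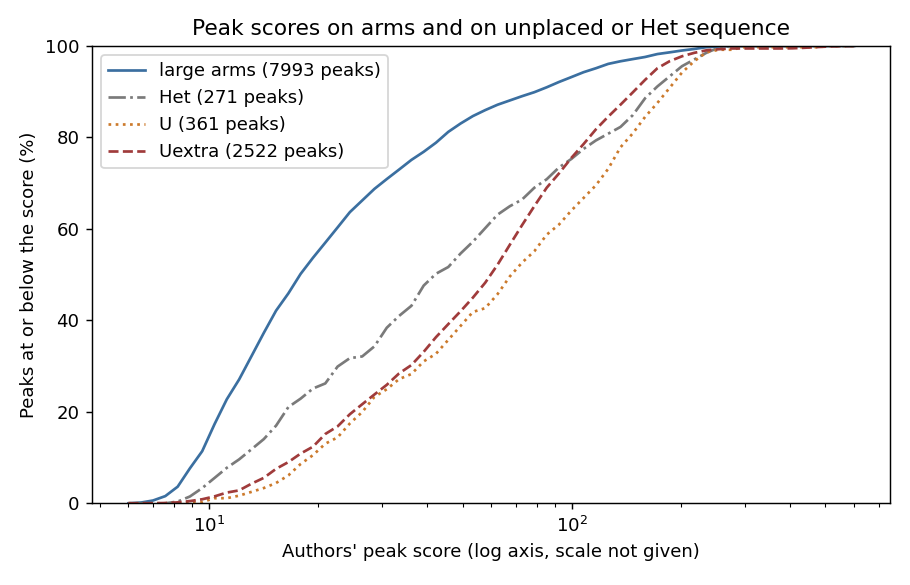
Percent of peaks at or below each score (vertical axis) against the authors' score (horizontal log axis, scale not given), with 1 line each for the 5 large arms, the Het scaffolds, U and Uextra. The lines of U and Uextra lie to the right of the line of the arms, with medians of 68.2 and 59.9 against 17.9.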

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

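All tests in this part were chosen after the result was seen. Peaks were present on sequences that the comparisons between arms leave out, and these are listed here for that reason. Since a caller lists only regions past its threshold, their presence tests nothing, and the input libraries were not used here. There were 2522 peaks on Uextra, 361 on U and 7 on YHet, a scaffold of Y heterochromatin. The 7 peaks on YHet had a median score of 59.4 and covered 8726 bases.

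The scores on the unplaced and Het sequences were high, and 2 technical explanations were tested. Wider peaks score higher in this list, but the peaks outside the arms were not wider. Their mean score percentile lay above that of the arms in 10 of 10 width classes of about equal size. The difference ran from 12.9 to 43.5 and was 32.0 on average, which argues against the called width as the cause. The widest peak of Uextra had 1774 bases, so the class from 2153 bases up, where the difference was 12.9, held none of its peaks. Repeat-rich sequence is a candidate explanation, since one unplaced scaffold may collect reads from many copies. It predicts higher scores in the repeat-rich 1 Mb of each large arm nearest the centromere, and there the mean score percentile per block was higher by 15.9 (95% interval 9.13 to 22.6, n = 45 against 920 blocks, p = 1e-05 by permutation, the smallest possible). The difference was positive on 4 of 5 arms and passed the adjusted threshold on 3 of them, while on 3R it was -5.63. Peak width was not held equal here, so this rise cannot tell repeat-rich sequence from wider peaks near the centromere. True enrichment of the mark on repeats and a higher copy number of repeats in these cells both stay open, since neither the input nor the ChIP reads were analysed here and no biological explanation was tested.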

How the results depend on the processing

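Of 41 repeats of the tests under another setting, 35 kept both direction and side of the threshold, and none reversed. Among the 35 were 9 repeats of clustering and 7 of score against width. Each of these had the smallest possible p, so they could hardly lose the call. X kept the call in 8 repeats and lost it in 2, and chromosome 4 kept it in 7 and lost it in 3. The exceptions were 6. Among the highest-scoring 25% of the peaks, X lay -0.24 points from the autosomal arms and chromosome 4 -2.43 points. Over blocks that hold a peak, X differed by -1.62 points and chromosome 4 by -5.37 points, with 5 blocks left on chromosome 4. Among peaks at or above the median score, chromosome 4 differed by -4.22 points. The stricter lists are smaller by construction, with 5621 and 2794 peaks, and hold a larger share of unplaced and Het sequence, 45.4% and 58.8%. Counted too are 3 repeats of the score percentile outside the arms on lists cut on the score, which hold the last of the 6 exceptions. Such a cut narrows the scores left, so these repeats, among them the loss of the call at 2.01 among the highest-scoring 25%, say nothing about whether that difference is stable. The repeats of score against width on the same lists, with rho of 0.18, 0.23 and 0.61, share this limit and were counted as kept. For the other losses the cause was not tested. Chosen after seeing the data were the list without peaks scoring over 100, the blocks from base 1, the removal of the proximal 2 Mb, the joined list of the 5 large arms and each setting for the score percentile outside the arms. Without peaks scoring over 100, the difference on X was -2.51 points. No paired analysis was possible because the 1 peak list used here carries no value per library, and for the same reason no replicate was left out. The reads of the 4 libraries were not analysed here. The alternatives for gene position, start sites, gene lists and sequence were not run, since no annotation or sequence of release 5 was used here. Since read depth was not analysed here, it stays open whether the empty blocks lack the mark or lack reads.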

Other observations

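The tests in this part were chosen after the result was seen, except the comparison of covered bases on X and its repeat among the highest-scoring 25% of the peaks. The peak nearest the telomere of each large arm was examined, since fly telomeres are known to be built from arrays of the retrotransposons HeT-A, TART and TAHRE in place of telomerase repeats. The last peaks of 3R and 2R had scores of 506 and 404 and lay at percentiles 99.96 and 99.87 of the list. The first peak of X, from 57201 to 58096, had a score of 104 and lay at percentile 88.7. The first peak of 2L, from 121 to 5590, had a score of 48.3 and lay at percentile 71.0, and the first peak of 3L, from 68 to 794, had a score of 18.7 and lay at percentile 40.8. Scores near the top of the list were thus seen at the telomeric end of 3R and 2R, while those of X, 2L and 3L were lower.

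One peak width recurred on the arms. Among the 391 peaks of 4000 bases or more, the window from 7468 to 7568 bases held 22 peaks against 4.49 expected when widths were jittered by up to 5%. This excess of 8.26 square roots of the expected count lay above the 5.85 reached at most in 1000 jittered draws (permutation by jitter, p = 0.001, the smallest possible). It argues against a chance coincidence of widths. The windows started at the observed widths in the draws too, so the highest excess of a draw may be understated and the p too low. The peaks lay on 2L (10), 2R (5), 3L (3) and 3R (4). Recurrence beyond this window was not shown. Over all 391 peaks, 1045 pairs differed in width by 20 bases or less, against 893 on average in the jittered draws (permutation by jitter, p = 0.002), but 140 of these pairs lay inside the window. Without its peaks, 903 pairs were left against 868 on average (permutation by jitter, p = 0.158). A candidate explanation is copies of a dispersed repeat that share reads, which predicts shared scores as well as a shared width. Pairs within the window differed in score by a median of 0.16 on the log2 scale, against 0.74 on average and 0.21 at least in draws of 22 from the 47 peaks within 10% of its widths (permutation by drawing, p = 0.001, the smallest possible). The median score was 230 in the window and 108 in the other 25 of these peaks. The high scores in the window were known before this test was chosen, and both deciding tests replaced earlier ones whose values had been seen, the pair count and a comparison of scores between all pairs of nearly the same width. The latter gave medians from 0.37 to 0.43 in 6 versions, against 0.57 to 0.58 with permuted scores, but without the window it covers peaks whose recurrence was not shown, so it bears on no explanation. Which sequence lies under these peaks was not analysed here. None of the 22 peaks lay on X, which held 62 of the other 369 wide peaks (Fisher's exact test, two-sided, p = 0.033, not adjusted).

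X had fewer bases in peaks than the pooled autosomal arms. A lower sequencing depth on X, of which these cells may carry fewer copies than of an autosome, predicts the loss of weak peaks and lower scores. The deficit was clear without the peaks scoring over 100, at -2.51 points, and small among the highest-scoring 25% of the peaks, at -0.24. The mean score percentile per X block minus that per autosomal block was 7.02 over all peaks. Without the proximal 1 Mb it was 6.90 (95% interval 2.51 to 11.2). The direction is not the one that lower depth predicts, but peak width was not held equal. The deciding value was also chosen after the values were known, so no conclusion on depth is drawn. As a check of the direction, autosomal scores were multiplied by factors from 0.9 to 0.4 and those under the lowest score of the list dropped. Ranked together with the unscaled scores, the mean percentile of the scaled scores was lower, by -4.37 to -16.8. Multiplying by less than 1 lowers scores by construction. The check thus shows only that dropping weak peaks did not undo this, and it assumes that scores scale with depth. The check ranks single peaks and not block means, so its size cannot be set against 7.02 or 6.90. Removing the peaks scoring over 100 left 1.93 (-2.08 to 5.93), and removing them with the proximal 1 Mb left 2.29 (-1.65 to 6.35), but such a cut on the score itself decides nothing. The test was first decided on that last value, which left depth open, and was moved to 6.90 after both values were known. Peaks scoring up to 100 were fewer on X, with a difference of -2.67 per 100 kb (95% interval -3.60 to -1.66), while those over 100 differed by 0.08 (-0.06 to 0.23). A lower depth, alone or together with high scores from repeats on X, stays open, as does a true difference of the mark. No biological explanation was tested, and 2L, an autosomal arm, was covered about as little as X.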
